A study of Symphysodon aequifasciata with 2 samples.

How the data were processed

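Brain tissue was taken from 1 male and 1 female discus of 1 year, killed in 100 mg/L MS-222, an anaesthetic, and frozen, per the labels. Total RNA with a RIN above 7.0 (5 µg) went through poly(A) selection and an unstranded Illumina library preparation with inserts of about 300 bp, within 50 bp, and was sequenced in paired ends. The submitters' processing notes name cutadapt, FastQC, Salmon and edgeR, without versions or roles. The feature identifiers have the form that the Trinity assembler gives, and no genome is named. The deposited values of each library are in TPM, in which reads are divided by a length and scaled to the same total in each library. TPM fixes the total, so a few strongly expressed features lower all others, and short features take their value from few reads. The lowest value of the higher library is 6.01 TPM, so features that stayed below this in both libraries are not part of the table. The authors' calls of differential expression were not used here.

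Libraries were grouped by the gender label, and columns were matched to libraries by title. The ratio of a feature is log2((female TPM + 0.5) / (male TPM + 0.5)), which understates the ratio of low features. Folds in the text are ratios of TPM without a pseudocount. A minimum of 1 TPM in the higher library was set, and it removed nothing. With 1 library per sex no test between sexes was possible, and no p-value is given. A feature was counted as apart at 2-fold.

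Before the data were examined, 25 gene lists with 365 genes were fixed. A feature belonged to a list gene if its symbol, or where it had none its protein name, matched. After the data were examined, 20 kinds of match to another protein were excluded on names alone, such as receptors matched for their hormones. Of the list genes, 230 were matched and are called measured, each represented by its matched feature with the highest mean. A list gene whose features carry another symbol or name counts as not measured. For lists with at least 3 measured genes the median, its 95% interval from order statistics (the whole range under 6 values) and its percentile among 10000 random lists were computed. Random lists were drawn from 12234 names, 1 feature each, in 20 bins of mean expression. The percentile describes these libraries and is not a test. Some list results are not reported here.

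Genes were named by a rule fixed before the data were examined. Its first part took named features with at least 0.5 TPM in the lower and 5 TPM in the higher library, and the 12 largest ratios per direction. The second took the 5 most abundant named features per direction with under 0.1 TPM in the other library. The third took, in each list, the 2 members with the largest ratio and the most abundant member. The fourth took cyp19a1b, gnrh1, gnrh3, avp, oxt, esr1, esr2, ar, gh, prl, lhb and fshb where measured, which left esr2, gh, prl, lhb and fshb out. Other genes in the text serve as further examples of a list or were chosen after their values were seen, among them those of the ranking at 500 bases, mch, mch2, AGRP, Nmb, sst2 and H2-K1.

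TPM holds no total depth. In both libraries, however, values of features of one length were whole multiples of one step, taken here as the worth of 1 read. For each of 180 lengths from 201 to 380 bases the step was found by a search for the period of the values. At 201 bases it was 1.11 TPM in the male and 1.23 TPM in the female library, and at 380 bases 0.20 and 0.23 TPM. The step fell faster than feature length rose, so the reads were not divided by the full feature length. Among values under 30 reads, 95.2% of 13487 in the male and 95.3% of 15120 in the female library lay within 0.1 of a whole number of reads, against 20% by chance. A feature of 201 bases at 6.01 TPM thus rests on about 5 reads. Reads recovered this way gave exact (Clopper-Pearson) 95% intervals of a fold. For longer features the step at 380 bases was used, which counts too few reads and widens the interval. These intervals cover counting error only, not the spread between fish, and they are too narrow if duplicate reads are present.

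Scripts ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The procedures were tested on simulated data. For the ratios over 12234 names, 100% of 200 features changed 4-fold were recovered past 2-fold, and 0.14% of unchanged features passed it. All were drawn at about the depth of features of 380 bases, so these rates do not hold for shorter ones. Among 18569 features of 201 to 380 bases, counting at equal levels would put 490 past 2-fold towards the female and 501 towards the male library. For the list percentiles over the same 12234 names, 7% of 200 unshifted lists fell outside the central 95%, and 100% of 100 lists shifted by 1 on the log2 scale lay above percentile 97.5. A shift of 1 is larger than any list median reported here, and the recovery of smaller shifts was not tested. Ratios were shuffled across names beforehand, so a link of ratio with expression was not simulated. For the read steps, the simulation over 18569 features recovered a step at 149 lengths, against 180 lengths in the data. The largest error of a recovered step was 0.55%. This error says nothing on the lengths without a recovered step. Alternatives covered centring on the median log2 ratio, pseudocounts of 0.25 and 5, no minimum and a minimum of 10 TPM, 1 feature per name, summed features per gene and a 4-fold threshold. Limits of 500 and 1000 bases, named features alone and random lists matched on length were added after the data were examined. Names come from matches to proteins of other species, and reads shared between paralogs or alleles may be split between features in ways that cannot be seen here.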

Results

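Poly(A) RNA from the brain of 1 male and 1 female discus, an ornamental cichlid (Symphysodon aequifasciatus), both aged 1 year, was sequenced as 1 library per sex. The design implies a single comparison, the female against the male brain, which asks which brain transcripts differ between the sexes. There were no replicates, so every difference below describes these 2 libraries. Sex could not be told apart from the individual fish, its handling or its library preparation, and the sex of each library follows its gender label, which none of the genes measured here checks. The titles begin with O for the library labelled male and with T for the one labelled female, and these initials, which are not explained, can be read as going against the gender labels. If the gender labels were swapped, every direction given here would turn. The deposited table holds 40209 assembled features, each a transcript cluster built from the reads without a genome. Of these, 13709 carry a gene symbol and 18927 a protein name taken from other species. The values are TPM, a measure of relative transcript abundance, and sum to 937828 in the male and 943014 in the female library. Each listed feature reached at least 6.01 TPM in one library or the other. The mitochondrial gene mt-co3 was the most abundant feature in both, at 10148 TPM in the male and 11608 TPM in the female library. The 10 most abundant features took 5.51% of the male and 6.02% of the female total.

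The clock repressor genes per3 and per1 were 4.15-fold and 3.52-fold higher in the male library, and the clock gene nr1d1 was 4.46-fold higher in the female library. Transcripts of pomca, which encodes the precursor of melanocortins, and of gnrh1, which encodes a gonadotropin-releasing hormone, were 5.15-fold and 2.12-fold higher in the female library. The pomca ratio rests on 6 and 28 reads, and the lower bound of its fold, set for 12234 names at once, was 0.81, so counting error is not excluded for it. A soluble guanylate cyclase similar to Gyc88E, an enzyme that makes cyclic GMP, measured 1.69 TPM in the male and 56.8 TPM in the female library. The lists of neuron, radial glia and myelin markers had medians of −0.05, 0.05 and 0.05 on the log2 scale.

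Over all features, 2019 were at least 2-fold higher in the female library and 4075 at least 2-fold higher in the male library, on the scale of log2(TPM + 0.5). The median log2 ratio of female over male was −0.07. Most of these differences lay in short features. Of the features of 201 to 250 bases, 11.7% were at least 2-fold higher in the female and 22.4% in the male library, against 0.25% and 0.89% of those of 2001 to 4000 bases. Among the 10726 features of at least 1000 bases, 40 were at least 2-fold higher in the female and 108 in the male library. Across features the log2 values of the libraries correlated with Pearson's r = 0.77, and with r = 0.96 over features of at least 1000 bases, where features are not independent replicates.

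**Figure D1:**
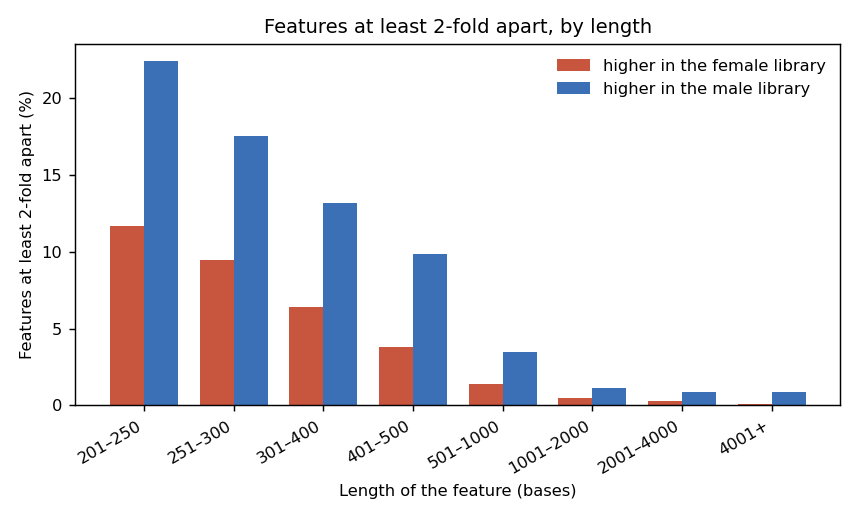
Percent of features (y axis) at least 2-fold higher in the female library (red) or in the male library (blue) for 8 classes of feature length in bases (x axis). The share falls from 11.7% and 22.4% at 201 to 250 bases to 0.10% and 0.87% at 4001 bases or more.

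Among named features with at least 0.5 TPM in the lower library, Gyc88E had the largest ratio towards the female library on the log2(TPM + 0.5) scale, 4.71 over a feature of 2920 bases (TRINITY_DN11791_c2_g6). Phosphodiesterase 9A (Pde9a), which breaks down cyclic GMP, measured 0.60 TPM in the male and 9.55 TPM in the female library, a log2 ratio of 3.19. A feature named hlh-13, whose protein match is the neuronal and pancreatic transcription factor PTF1A, measured 0.58 and 10.3 TPM. The developmental gene HMX2, a homeobox gene, measured 2.29 and 24.4 TPM, and ptch1, a feature matched to a Hedgehog receptor of the patched family, measured 1.45 and 17.6 TPM. The extracellular matrix protein hemicentin-1-like was the most abundant of these, at 44.6 TPM in the male and 396 TPM in the female library. The phosphatase PTP4A3 measured 1.00 and 16.8 TPM. Features for aquaporin-3-like, Amy2 (a pancreatic amylase), TDRD12, CXCR3 and Slc27a2 completed the 12, with log2 ratios of 4.71, 4.39, 3.82, 3.71 and 3.14. These 5, HMX2 and ptch1 were 202 to 288 bases long and rested on 1 to 3 reads in the male library. The exact 95% interval of the fold ran from 6.30 to 1527 for aquaporin-3-like and from 2.99 to 107 for ptch1.

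Of the 12 features with the largest ratio towards the male library by the same rule, 10 were at most 380 bases long. The largest of these ratios belonged to a feature of 292 bases for a zinc finger protein like Gfi-1, at 23.0 TPM in the male and 0.52 TPM in the female library, or 49 reads against 1. The immune genes included WDFY4, a WD repeat and FYVE domain protein, at 20.1 and 0.52 TPM. An immunoglobulin light chain measured 209 and 10.5 TPM, and an immunoglobulin mu heavy chain 19.3 and 1.25 TPM. The inositol trisphosphate receptor gene ITPR2, which encodes a calcium channel of internal stores, measured 19.5 and 1.14 TPM. A feature for a protein that interacts with this receptor type measured 19.3 and 0.85 TPM. The transcriptional corepressor Bcor had a log2 ratio of −4.19, ARHGEF10L −3.72, nucleolar protein 8 −3.54, ADAMTS2-like −3.53, AHCYL2 −3.48 and protocadherin Pcdhb8 −3.45.

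Ranked again among features of at least 500 bases, a choice made after the data were examined, the male side was led by TLF1 (matched to a trypsin), Cd22 (matched to the adhesion protein VCAM1) and ttll3, a tubulin-modifying enzyme. Their values in the male and female libraries were 8.0 and 0.72 TPM, 40.02 and 6.4 TPM, and 21.3 and 3.40 TPM. The ubiquitin ligase HUWE1 measured 21.8 and 4.1 TPM and the mitotic kinesin Kif23 8.55 and 1.41 TPM. On the female side, behind Gyc88E, hlh-13 and Pde9a, came mch2, a melanin-concentrating hormone gene, at 7.02 and 44.3 TPM. A feature of the clock gene ARNTL2 measured 1.06 and 7.87 TPM and the appetite peptide AGRP 1.76 and 10.8 TPM. The homeobox gene Nkx2-4 had a log2 ratio of 2.12 and the second melanin-concentrating hormone gene, mch, of 2.10.

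Some abundant features were listed at 0 in one library. Listed at 0 in the female library were an MHC class I antigen, at 159 TPM in the male, and features of AHCYL1 and AHCYL2, relatives of S-adenosylhomocysteine hydrolase, at 40.2 and 21.5 TPM. Both, and the AHCYL2 feature ranked above, share the identifier stem TRINITY_DN11658_c1 and the same protein match, so they may not be separate genes. The F-box protein Fbxo40 and an IgE receptor subunit were also at 0 there, against 24.8 and 23.2 TPM in the male library. In the male library, a thymic-like parvalbumin measured 0 against 64.2 TPM in the female, and a feature matched to proteasome subunit beta type-8 0 against 33.5 TPM. Another feature of that subunit, PSMB8, measured 19.5 TPM in the male and 22.9 TPM in the female library. A type I keratin, the nucleotidase Nt5c1a and a pancreatic amylase were at 0 in the male and at 26.1, 22.0 and 17.9 TPM in the female library. This amylase and Amy2 above share the identifier stem TRINITY_DN13518_c6. Of 34 features with pancreatic amylase or trypsin in their protein name, a group formed after the data were examined, 24 lay within 2-fold. The match was on text anywhere in the name, so the group may hold proteins that are not pancreatic enzymes. At least 2-fold higher were 4 in the female and 6 in the male library, and the sums were 495 and 558 TPM.

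Of 18 clock genes fixed, 16 were measured; 5 were at least 2-fold higher in the male library, 1 was at least 2-fold higher in the female library, and 10 lay within 2-fold. The period genes, which repress their own activators, measured 49.2 TPM (per3), 18.6 TPM (per1) and 8.92 TPM (per2) in the male library. In the female library they measured 11.9, 5.28 and 6.01 TPM. The repressor genes cry2, bhlhe41 and nr1d2 had log2 ratios of −1.51, −1.33 and −1.05, and bhlhe40, the most abundant member, one of −0.63. The activator genes arntl2, clock and arntl had log2 ratios of 0.76, 0.62 and 0.46. Among repressors, nr1d1, which represses arntl, and cry1 were also higher in the female library, at 3.47 and 15.5 TPM and at 39.3 and 48.7 TPM. The median of the list was −0.58 (95% interval from order statistics −1.33 to 0.46) and −0.30 at a minimum of 10 TPM. It fell at percentile 0.01 of 10000 random lists matched on mean expression, whose central 95% ran from −0.26 to 0.13. The 95% interval of the male-to-female fold, for counting error alone, was 3.09 to 5.77 for per3, 2.23 to 5.88 for per1 and 1.64 to 7.05 for cry2. That of rora, with exact reads of 22 and 20, held 1. Those of per2, arntl and tef also held 1, but their reads were counted with the step of a shorter feature. This counts too few reads and widens the interval, so counting error is not decided for per2, arntl and tef. The features with the symbols PER3, CRY2 and ARNTL2 have protein matches named as period 2-like, cryptochrome-1 and ARNTL-like protein 1, so the assignment within these families is uncertain, and the labels used here do not give the time of day of sampling.

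**Figure D2:**
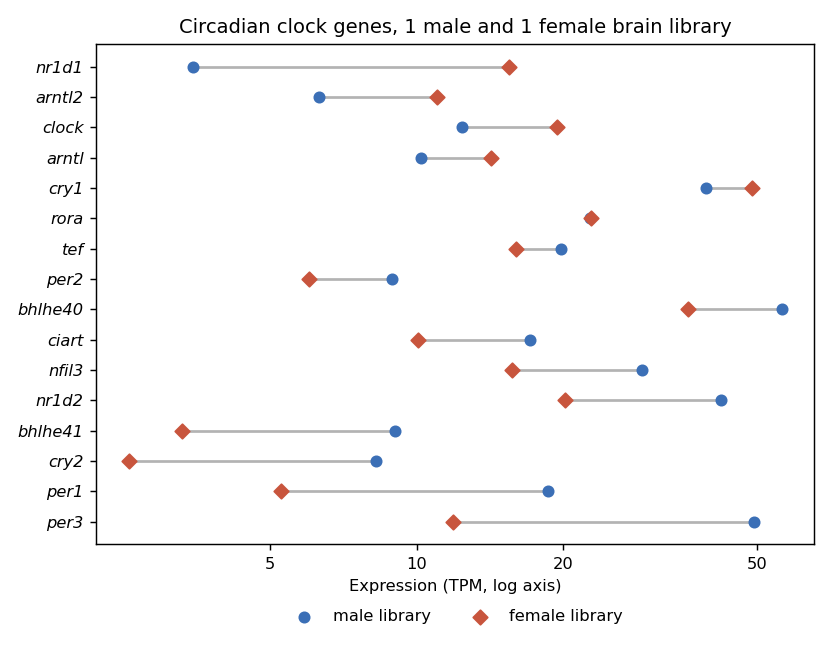
TPM (x axis, log scale) of the 16 measured clock genes (y axis, ordered by ratio) in the male library (blue circles) and the female library (red diamonds), 1 library each. The period genes per3 and per1 sit at 49.2 and 18.6 TPM in the male against 11.9 and 5.28 TPM in the female library, while nr1d1 sits at 3.47 and 15.5 TPM.

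Among neuropeptides and their receptors, 18 of 24 were matched and 13 of these were higher in the female library, 2 of them at least 2-fold. None was at least 2-fold higher in the male library. The list gene pmch was not matched, because its features carry the symbols mch and mch2, with pro-MCH as protein match. They measured 7.53 and 7.02 TPM in the male and 33.96 and 44.25 TPM in the female library. The counts and the list median leave both out. The list median was 0.20 (95% interval −0.13 to 0.51), at percentile 99.75 of matched random lists. It was 0.13 at a minimum of 10 TPM and 0.08 over members of at least 1000 bases. The gonadotropin-releasing hormone genes gnrh1, gnrh2 and gnrh3 measured 21.5, 3.89 and 36.1 TPM in the male library. In the female library they measured 45.5, 10.1 and 43.6 TPM. The 95% interval of the fold was 1.56 to 2.89 for gnrh1 and 1.48 to 4.68 for gnrh2, while that for gnrh3 held 1, at 0.98 to 1.49. The reads of gnrh3 were counted with the step of a shorter feature, which widens its interval, so counting error is not decided for it. Vasotocin (avp), the fish relative of vasopressin, measured 37.99 TPM in the male and 53.7 TPM in the female library. Isotocin (oxt), the relative of oxytocin, measured 287 and 253 TPM. The most abundant member, npy, measured 347 and 277 TPM. Of the 8 pituitary hormone genes only pomc was measured, as pomca, with 6 reads in the male and 28 in the female library and a 95% interval of the fold of 2.10 to 15.3.

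**Figure D3:**
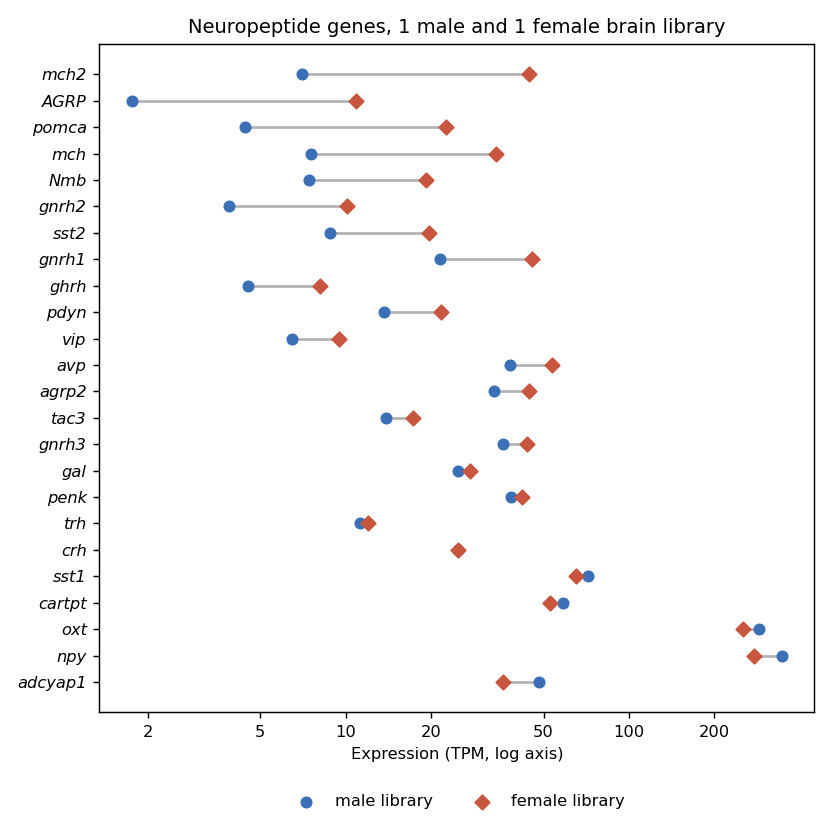
TPM (x axis, log scale) of neuropeptide genes (y axis, ordered by ratio) in the male library (blue circles) and the female library (red diamonds), 1 library each. The 18 list members are shown with pomca, from the pituitary hormone list, and with 5 related features picked after their values were seen (mch, mch2, AGRP, Nmb and sst2). These 6 additions all sit higher in the female library.

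Genes of sex steroid synthesis and steroid receptors went both ways. Of 18 fixed, 10 were measured, 6 with a ratio above 0 and 4 below, and the median was 0.05 at percentile 82.4. It was 0.15 at a minimum of 10 TPM, 0.13 after centring and 0.01 over members of at least 1000 bases. Brain aromatase, which makes oestrogen from androgen and was matched here by the symbol cyp19a1, measured 8.69 TPM in the male and 4.97 TPM in the female library. The 95% interval of its female-to-male fold, 0.33 to 1.00, reached 1. Its reads were counted with the step of a shorter feature, which gives too few and widens the interval. Whether counting error covers this difference is therefore not decided. The symbol does not tell the brain form from the gonadal form. The androgen receptor ar measured 24.5 and 10.2 TPM over 24 and 9 reads, and the oestrogen receptor esr1 7.73 and 5.66 TPM over 35 and 23 reads. The 5-alpha reductases, which make dihydrotestosterone, pointed in opposite directions, with a log2 ratio of 1.39 for srd5a2 and −0.91 for srd5a1. Of 13 genes of gonadal sex differentiation 4 were measured, all within 2-fold. Their median of −0.06 changes sign when the values are centred. The largest ratio was that of sox9, at 7.47 and 13.2 TPM, followed by nr0b1 at 10.1 and 7.24 TPM, and sox3 was the most abundant at 40.01 and 37.6 TPM.

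Of 17 heat shock and stress response genes 12 were measured and 10 were higher in the male library, with a median of −0.15 (95% interval −0.40 to −0.06) at percentile 2.93. This median lay inside the central 95% of random lists, −0.16 to 0.19, and was −0.08 after centring. The glucocorticoid-induced chaperone gene fkbp5 stood out at 75.4 TPM in the male and 25.6 TPM in the female library, a log2 ratio of −1.54. The stress-induced inhibitor of growth signalling ddit4 had a log2 ratio of −0.58, and the most abundant member, the chaperone hspa8, measured 381.4 and 361.7 TPM. Immediate early genes, which neurons switch on with activity, went both ways. Of 19, 13 were measured, with a median of −0.14 at percentile 22.8 (−0.07 after centring), 5 above and 8 below 0. The nuclear receptor nr4a1 measured 6.11 TPM in the male and 1.71 TPM in the female library and npas4 15.8 and 8.34 TPM. By contrast jun measured 20.2 and 36.9 TPM and fos 18.97 and 27.1 TPM. The most abundant, egr1, measured 48.9 and 34.7 TPM.

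Neuron markers as a group were close to equal, with 13 of 14 measured and a median of −0.05, a sign that changes when the values are centred. The RNA-binding protein gene elavl3 measured 52.7 TPM in the male and 25.9 TPM in the female library and the neurofilament nefm 109 and 73.1 TPM. The synaptic gene snap25, the most abundant, measured 2201 and 2642 TPM. Genes of glutamate and GABA signalling were all measured, 17 of 17, and each was within 2-fold, but 14 were higher in the male library. Their median was −0.24 (95% interval −0.38 to −0.09) at percentile 0.54. The glutamate receptor subunits grin2a and gria2 had log2 ratios of −0.52 and −0.46, and the most abundant member, the GABA receptor subunit gabrb2, went the other way at 142 and 163 TPM. Among 11 measured of 16 monoamine and acetylcholine genes, the median was −0.09 at percentile 36.7, and 0.01 at a minimum of 10 TPM. The dopamine synthesis gene th measured 10.6 and 24.3 TPM and the serotonin synthesis gene tph2 17.8 and 7.85 TPM, both on features of under 300 bases, and the acetylcholine-degrading enzyme ache was the most abundant at 19.6 and 18.4 TPM.

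The 11 measured radial glia and astrocyte markers of 12 had a median of 0.05 at percentile 48.4 (0.13 after centring), all within 2-fold. The intermediate filament gene vim measured 17.5 and 26.6 TPM and the fatty acid binding protein gene fabp7, the most abundant, 1652 TPM in the male and 2443 TPM in the female library. Of 13 oligodendrocyte and myelin markers 9 were measured, with a median of 0.05 at percentile 68.2, and 0.26 over members of at least 1000 bases. The most abundant, mbp, measured 716 and 909 TPM, and olig1 and cldn19 had log2 ratios of 0.48 and 0.44. Microglia and macrophage markers were lower in the female library in 8 of the 10 measured of 13, with a median of −0.25 at percentile 3.94. The microglial growth factor receptor csf1r measured 25.9 and 13.8 TPM and the complement gene c1qc 16.4 and 9.01 TPM. The most abundant member, apoe, measured 812 and 901 TPM. Vascular and meningeal markers had a median of 0.13 at percentile 93.7 over 12 of 15 (0.20 after centring, 0.07 with summed features), led by the collagen gene col1a1 at 3.82 and 13.3 TPM, with cldn5 the most abundant at 27.5 and 35.4 TPM.

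The alpha globin hba measured 305 TPM in the male and 644 TPM in the female library and the beta globin hbb 520 and 1043 TPM. Of the other red blood cell markers alas2, an enzyme of haem synthesis, and epb41 were also higher in the female library, at 8.52 and 15.1 TPM and at 26.9 and 42.2 TPM. The remaining 4, ca1, tfrc, nt5c3 and slc4a1, had log2 ratios of −0.33 to −0.12. The median of the 8 measured of 9 was 0.26 (95% interval −0.33 to 1.08) at percentile 98.4, and 0.02 when the features of a gene were summed. Among 14 lymphocyte and antigen presentation genes 10 were measured, with a median of −0.16 at percentile 16.1 and 3 at least 2-fold higher in the male library. Over members of at least 1000 bases, a limit added after the data were examined, the median was 0.23. The 3 were the MHC class I feature mhc1 at 128 and 17.3 TPM, the T-cell gene cd4 at 27.6 and 7.86 TPM and the MHC class II gene mhc2a at 7.77 and 3.50 TPM. Another MHC class I feature, with the symbol H2-K1 and named after its values were seen, went the other way at 193 and 788 TPM. A further feature with this symbol measured 118 and 94.1 TPM. Because they carry a symbol, the H2-K1 features were not matched to mhc1 by their protein names, although their means are higher. The list gene ighm was not matched, although a feature named immunoglobulin mu heavy chain measured 19.3 and 1.25 TPM. The list median leaves out the H2-K1 and immunoglobulin mu features and depends on this matching. The shared MHC class I chain b2m, the most abundant, measured 1207 and 1029 TPM. The 8 measured of 18 interferon and innate immune genes had a median of −0.12 at percentile 24.0, which was −0.05 after centring and −0.03 with summed features. In this list usp18 measured 19.5 and 6.64 TPM and il1b 6.58 and 13.3 TPM.

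**Figure D4:**
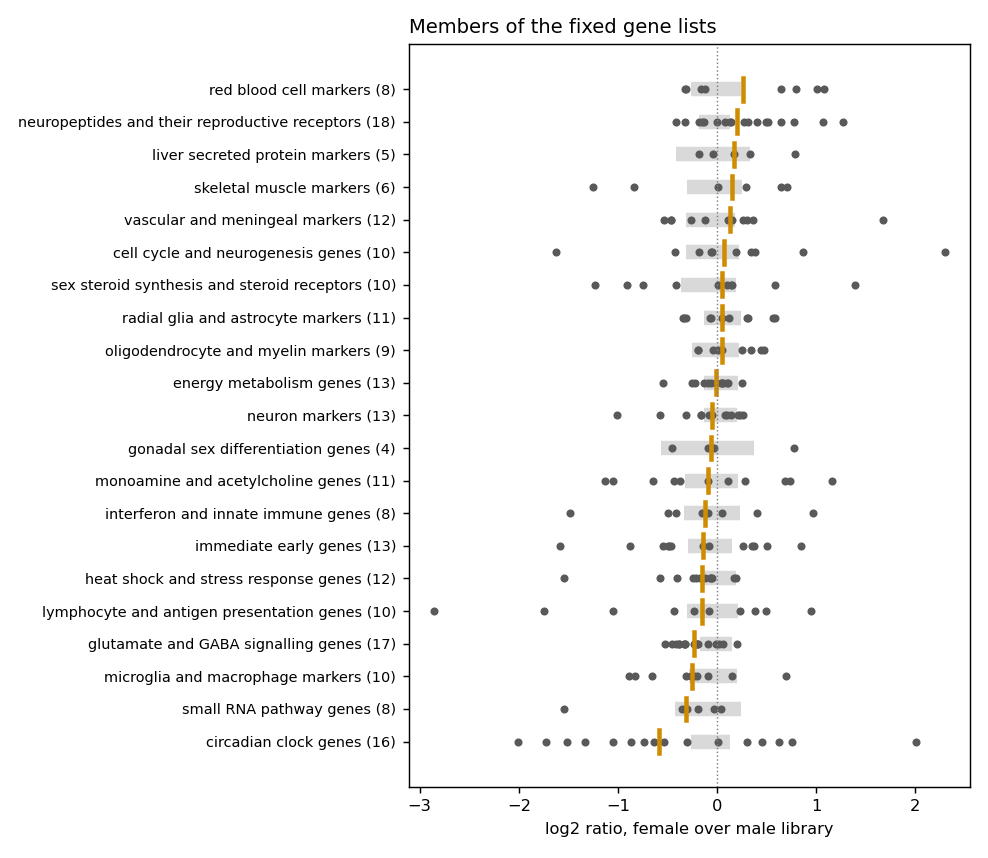
Log2 ratio of the female over the male library (x axis) for the measured members (dots) of 21 fixed gene lists (y axis, number measured in brackets). Orange bars are list medians and grey bands the central 95% of medians of 10000 random lists matched on mean expression. The clock list has its median at −0.58, outside a band of −0.26 to 0.13.

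Energy metabolism genes, 13 of 17 measured and all within 2-fold, had a median of −0.01, a sign that changes when the values are centred. Its most abundant member gapdh measured 879 and 870 TPM, and the glucose transporter slc2a1 had the largest ratio at 22.7 and 15.4 TPM. Small RNA pathway genes were lower in the female library in 7 of 8 measured of 12, with a median of −0.31 at percentile 7.53 (−0.20 with a pseudocount of 5). The Argonaute gene ago3 measured 31.96 and 10.6 TPM over a feature of 208 bases, and tnrc6b, the most abundant, 27.3 and 28.0 TPM. Cell cycle and neurogenesis genes had a median of 0.07 at percentile 79.5 over 10 of 16. It was 0.26 at a minimum of 10 TPM, 0.14 after centring and 0.13 with summed features. The cyclin ccna2 measured 3.24 and 17.9 TPM, nes, a marker of neural progenitors, 9.36 and 2.69 TPM, and neurod1, the most abundant, 80.8 and 105.15 TPM. Skeletal muscle markers, 6 of 12 measured, had a median of 0.15 at percentile 89.8, with myoglobin (mb) the most abundant at 1116 and 1746 TPM and tnnt3 at 24.7 and 10.1 TPM. Liver secreted protein markers, 5 of 12 measured, had a median of 0.17 at percentile 86.7, with apoa1 at 325 and 366 TPM and fetub at 6.28 and 11.2 TPM. Of 17 photoreceptor and pineal markers 2 were measured, rbp3 at 17.8 and 11.8 TPM and rho at 11.7 and 12.2 TPM, and of 12 germ cell genes none was matched.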

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

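The length limits, the restriction to named features and the random lists matched on length were chosen after the data were examined. The other settings were fixed before. The counts of features at least 2-fold apart, 2019 higher in the female and 4075 in the male library, moved by over 1.5 times under 6 settings. They were 767 and 1683 with a pseudocount of 5, 367 and 715 with 1 feature per gene name, 324 and 773 at 4-fold, 584 and 1222 over named features, 127 and 325 at 500 bases or more, and 40 and 108 at 1000 bases or more. Each of the last 5 looks at fewer features or asks for more, and a larger pseudocount shrinks ratios of low features by construction. The female share of the features apart stayed between 27.0% and 39.6% over all settings, the highest after centring (2357 and 3601). All 148 alternative values of the 22 list medians stayed inside the 95% interval of the main median, but these intervals are wide. Of the 22 medians, 5 changed sign and 17 changed sign or moved by over 1.5 times under at least 1 setting, 13 of them with centring. At a minimum of 10 TPM the clock median was −0.30 and the monoamine median 0.01. Over members of at least 1000 bases the lymphocyte median was 0.23, and the neuron and energy medians were both 0.01. With summed features the red blood cell median was 0.02. Of 512 alternative values of 104 named genes, none changed the sign of a ratio of at least 2-fold, but none of these settings could have done so. A pseudocount keeps the sign, a minimum leaves the value as it is, and centring only takes off the median of −0.07. Of the 512 values, 48 moved by over 1.5 times, 38 with a pseudocount of 5 and 10 with one of 0.25. Dropping the minimum left out no feature, so that setting tested nothing. Matching random lists on length as well put the clock list at percentile 0.01, the neuropeptide list at 98.2, the glutamate and GABA list at 0.54 and the stress list at 3.56. The microglia list moved from percentile 3.94 to 1.91, outside the central 95%. No paired analysis was possible because each sex has 1 library. For the same reason no library could be left out in turn, and size factors from counts were not run because the values are TPM. Depth limits the short features most: at 201 bases 1 read was worth 1.11 TPM in the male and 1.23 TPM in the female library.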

Other observations

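The gene groups in this paragraph were chosen after the data were examined. Cytosolic ribosomal protein genes were higher in the female library almost without exception, 65 of 67, with none at least 2-fold apart. Their median log2 ratio was 0.31 (95% interval from order statistics 0.28 to 0.33), above the range of 0.02 to 0.16 of matched random lists. Among 152 deposited KEGG pathway names with at least 10 genes, the ribosome also had the highest median, 0.24 over 126 genes. The lowest median was −0.54, of the intestinal IgA network over 28 genes. Next came globo-series glycosphingolipid synthesis, fatty acid synthesis and cytokine receptor interaction, with −0.39, −0.36 and −0.26 over 10, 13 and 114 genes. Of the cytokine receptor interaction genes 18 were at least 2-fold higher in the male library and 3 in the female. Guanylate cyclase 88E and phosphodiesterase 9A were looked at again because both were among the 12 largest ratios towards the female library. The 2 features of the cyclase summed to 1.87 TPM in the male and 75.2 TPM in the female library. Of 6 features matched to the phosphodiesterase, 5 were at least 2-fold higher in the female library and 1 lay within 2-fold, with sums of 17.3 and 52.9 TPM.

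All 6 features named as haemoglobin subunits were at least 2-fold higher in the female library, with sums of 1073 TPM in the male and 2331 TPM in the female library, and the alpha-D subunit HBAD measured 6.70 and 47.95 TPM. Immunoglobulin chains went both ways, with 5 of 20 features at least 2-fold higher in the female and 7 in the male library, and summed to 3342 and 6520 TPM. Of 7 MHC class I features 2 were at least 2-fold higher in the male and 1 in the female library, the last being the H2-K1 feature at 193 and 788 TPM, and the 7 summed to 1613 and 1582 TPM. The chaperone gene Dnajb5 measured 162 and 57.8 TPM, and the homeobox genes Shox2 and Gsx1 had log2 ratios of 1.44 and 1.46.

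In the 3 patterns that follow, the tests were chosen after the result was seen, except those of counting error in the last pattern. The first pattern is the spread of the clock genes, although on length-matched lists the median absolute ratios of other lists also lay high, among them immediate early, red blood cell, radial glia and lymphocyte genes at percentiles 99.7, 99.6, 98.6 and 97.7. Counting error on short features is argued against by the 14 members of at least 1000 bases, whose median absolute log2 ratio of 0.75 lay at percentile 100 of random lists of such features, and 5 of which were at least 2-fold apart against 1.18% of 6586 names. A scaling difference would move all members alike, whereas their median deviation of 0.82 from the list median lay above the range of 0.08 to 0.30 of matched random lists, at percentile 100. A difference in the time of day at sampling would set activators against their targets, and the median of clock, arntl and arntl2 lay 1.52 above that of 10 target genes, although nr1d1 among the targets, and the repressor cry1 outside them, went with the activators. It cannot be told apart from a difference between the sexes or between these 2 fish, because each sex is 1 fish and the labels used here give no hour, so a difference in sampling time may be the first thing to check.

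The second pattern is the excess of features at least 2-fold higher in the male library, 66.9% of all features apart. Binomial counting at equal levels favours neither library, with 501 features of 201 to 380 bases expected in the male and 490 in the female library, whereas the observed male share was 65.8% (exact 95% interval 64.5 to 67.1), which argues against counting error as the cause of the imbalance. Centring leaves a male share of 60.4% (exact 95% interval 59.2 to 61.7), which argues against one scaling factor common to all features as the whole cause. The median log2 ratio was −0.20 at 201 to 250 bases, −0.01 at 501 to 1000 and −0.10 at 4001 or more. Centring on one median of −0.07 therefore leaves the shortest features shifted towards the male library. More RNA without a protein match, such as unspliced or non-coding RNA, is argued against as the whole cause by a male share of 67.3% (64.4 to 70.1) among features of at most 300 bases with a protein name, against 64.6% among those without. The intervals of these shares treat features as independent, and they are too narrow where fragments of one gene are counted apart. Duplicate reads, the splitting of reads among fragments of one gene, and a difference between the fish may each contribute and were not tested.

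The last pattern is the higher level in the female library of mch, mch2, AGRP and pomca, 4 peptide genes picked for their log2 ratios of 2.10 to 2.57, while the feeding peptides npy, cartpt and agouti-related protein 2 had −0.33, −0.15 and 0.40. A larger share of the whole hypothalamus in the female sample would raise its other peptides alike, but avp, oxt, crh, trh, gal and ghrh had a median of 0.11 and a highest value of 0.78, and gnrh1, outside these 6, had 1.06. Counting error is argued against for mch, mch2 and AGRP, whose lower bounds of the fold, set for 12234 names at once, were all above 1, the lowest being 1.42. For pomca, with 6 and 28 reads, that bound was 0.81, so counting error among many features stays open and cannot be told apart from a difference in level. A different part of the hypothalamus in the dissection was not tested and stays open. The homeobox genes HMX2, Nkx2-4 and Gsx1 were also higher in the female library, at 3.16, 2.12 and 1.46. They were named for their high ratios, HMX2 rests on 3 and 29 reads, and other homeobox genes were not tallied, so they do not decide it. Feeding state and sex, which were not tested, may also underlie mch, mch2 and AGRP.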
